A study of Homo sapiens with 12 samples.

How the data were processed

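RNA was measured in 12 sections of OCT-embedded human kidney tumour, all labelled clear cell renal carcinoma, the commonest kidney cancer in adults. Per the labels' protocols, stranded poly-A libraries were sequenced as paired reads of 100 bp at a stated depth of 50M. The labels give 1 group of 12 and no further condition, so no groups were compared. The labels do not say that the 12 samples came from separate patients, so p-values of correlations and slopes measure only the spread between these samples. The p-values of list spread compare a list with random gene lists in the same samples. Replicate numbers follow accession order and are names only.

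The authors deposited a gene table of 26730 entries and an isoform table of 73599 entries. Per the submitters' processing notes, TopHat, RSEM and Bowtie2 and the build hg19 were used, and the role and version of each tool are not given in the sources used here. The unit of the deposited values was inferred to be FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), since no label names it. Column totals ran from 469735 to 556930 and were not equal, which TPM would be. FPKM keeps no total count, so the sequencing depth behind each value is unknown. Among 369 olfactory receptor genes the commonest nonzero value was 0.08 in 9 tumours, and it ranged from 0.02 to 0.16 and rested on 1 to 11 genes per tumour, too few to give relative depth. No interval from counts was computed.

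The 6229 entries named only by a transcript identifier and 80 symbols of XIST, TSIX and the Y chromosome were left out of all tests. Of the other 20421 genes, 13285 with a median of at least 1 FPKM counted as expressed, and values were analysed as log2(FPKM + 1). A difference on this scale understates the change of low genes. Gene type, genomic span and transcript length came from GENCODE release 29 (GRCh38) by symbol, with older symbols matched, and 12971 expressed genes (97.6%) had a match. Positions are given on GRCh38 from that annotation, while the authors' values were made on hg19.

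Before the data were examined, 29 gene lists, 12 pairs of lists, the tests and the rule for named genes were fixed. Lists needed 3 expressed members, which left 27. The loop of Henle, distal tubule and collecting duct list had 1 expressed member and the adipocyte list 2, and neither was scored. A list score was the mean over members of log2(FPKM + 1) minus each gene's mean over the 12 tumours. The SD of each score was compared, one-sided, with 10000 random lists matched on mean expression in 20 bins, for which the smallest possible p is 0.0001. The length index of a tumour was the mean centred value of the 10% of expressed protein-coding genes with the longest span (1272 genes of at least 163.2 kb) minus that of the shortest 10% (up to 5.79 kb). Genes of a list were left out of the index correlated with it. Correlations had two-sided permutation p-values from 100000 resamples. Slopes of each gene on the standardized length index or cytotoxic score were fitted with limma 3.58.1 (trend) in R 4.3.3, with 100 random orders of the score. All p-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

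Named genes were the 20 with the largest SD of log2 value among genes with a median in the upper part of the expressed genes, divided at the median. Each list added its 2 members of highest mean and its 1 of largest SD. Each slope test added the 10 genes of smallest p per direction past the threshold, or 3 per direction where none passed. Genes with common germline deletions or haplotype-bound expression and receptor segments of B and T cells were not named. Some genes that the rule selects are not reported here. Genes outside this rule were named after their values were seen in the account of the adrenal-type library, among the endothelial slopes on the length index and in the closing section.

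The design had foreseen a count model or, for normalized values, limma, and the second applied. The isoform table does not pair transcripts with genes, so the planned mean entropy over genes was replaced by the entropy of all isoforms minus the entropy of all genes, in bits. The alternatives tried were median-of-ratios rescaling, a pseudocount of 0.25, a minimum median of 10, no filter, z-scores, other definitions of the length index, limma without trend, and leaving out each tumour. Lists of adrenal cortex, adrenal medulla and renal genes were written after 1 library was seen to stand apart, and results without that library were then brought into the text.

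The tests were tested on simulated data with the real means and SDs. All 14 lists given a shared factor were called. With no shared factor, 7 of 27 lists were called when each gene kept its own SD, and 0 when SDs were shuffled or values were z-scored. The spread test therefore calls lists with variable members as well as lists whose members vary together. Of 200 genes given a slope, among 13285 genes, limma recovered 87% of those changed by 2 SD and 17% of those changed by 1 SD, called 6 unchanged genes, and called 0 genes when none was changed. Of 500 unrelated pairs, 4.2% had a permutation p under the threshold.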

Results

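Poly-A RNA was profiled in 12 OCT-embedded kidney tumour samples labelled clear cell renal carcinoma, and the deposited values are FPKM per gene and per isoform. Between 12478 and 13680 named genes reached 1 FPKM in each tumour. Spearman correlations between tumours over expressed genes ran from 0.695 to 0.934. The series title names a loss of epigenetic and transcriptional fidelity and resistance to immunotherapy, and its design text mentions a sample class that the labels assign to no tumour. The tumours were therefore described as 1 group, by what varied between them and what varied together.

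In 11 of the 12 libraries, genes of renal epithelium and clear cell carcinoma were high, and 1 library did not match its group's labels. CA9, a HIF-induced carbonic anhydrase on chromosome 9 (35673856 to 35681159), was between 99.4 and 279.7 FPKM in the 11 and 0.28 in that library. PAX8, a kidney lineage transcription factor, was between 12.02 and 65.8 FPKM in the 11 and 0.83 there, and all 14 genes of the renal list were below every other library. Genes of adrenal steroid synthesis were high in that library instead. STAR, which carries cholesterol into mitochondria (chromosome 8, 38143649 to 38151265), was at 6864 FPKM against a median of 2.45 in the other 11. CYP11B1 was at 1263 against 0.40, CYP21A2 at 1628 against 4.71 and SULT2A1 at 937.9 against 0.34. CYP21A2 has a near-identical pseudogene, so its level is uncertain. HSD3B2, MC2R and CYP11B2 stayed under 1 FPKM there and FDX1, at 8.87, lay within the range of the others. This library, called adrenal-type here, correlated with the others at 0.695 to 0.751, and the other 11 correlated with each other at 0.782 to 0.934. Entries with no gene name took 25.6% of its FPKM and 5.98% to 13.4% in the others. Results below are given for all 12 libraries, and the main counts also without it.

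**Figure D1:**
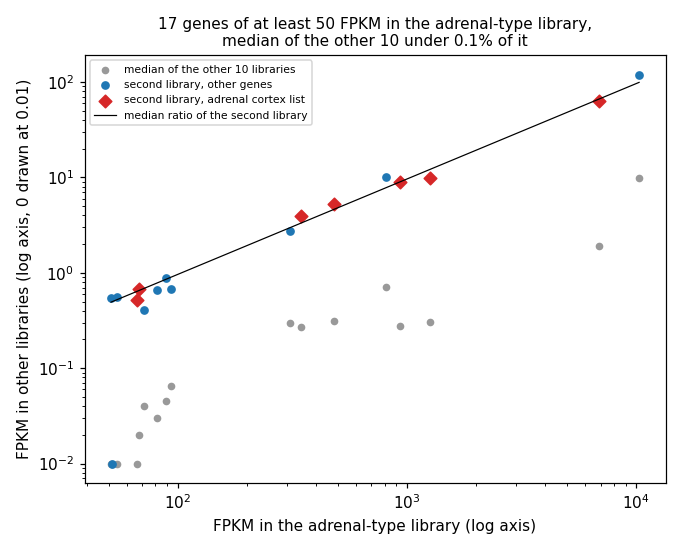
FPKM of 17 genes of at least 50 FPKM in the adrenal-type library (horizontal, log axis), chosen for a median in the other 10 under 0.1% of that level, against their FPKM in the library with the next trace of them and the median of the other 10 (vertical, log axis, 0 drawn at 0.01). In that second library 16 of the 17 genes lie at 0.574% to 1.25% of the adrenal-type level, and INS-IGF2 is listed at 0. KLK11 is at 97.8% of the adrenal-type level in 1 of the other 10, which their median does not show.

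The 20 most variable abundant genes were not tested as a class. SAA1, an acute phase protein, had a mean of 361 ± 934 FPKM (SD, n = 12) and a range of 0.14 to 3281. TGFBI, an extracellular matrix protein, was at 1063 ± 1659 FPKM (range 32.5 to 5223) and REG1A at 168 ± 411. KRT19, a keratin of simple epithelia, was at 232 ± 625 FPKM and CCL18, a macrophage chemokine, at 88.4 ± 241. SFRP2 was at 44.4 ± 54.7 FPKM. Tubule transporters and enzymes were among them, with SLC17A3 at 152 ± 222, DDC at 30.9 ± 32.8, NAT8 at 199.7 ± 175 and BBOX1 at 90.3 ± 84.3 FPKM. CDHR5 was at 69.0 ± 84.3, ABP1 at 202 ± 230, PNCK at 110.2 ± 113, PRAP1 at 49.9 ± 106 and CXCL14 at 247 ± 266 FPKM. In SAA1, KRT19, REG1A, CCL18 and PRAP1, 1 library held more than the other 11 summed. The rest of the libraries were at 95.8 ± 170, 52.6 ± 67.5, 53.7 ± 117, 19.2 ± 23.3 and 19.8 ± 19.3 FPKM. TGFBI and SLC17A3 were at 685 ± 1067 and 98.4 ± 128 FPKM without their highest library. SLPI and IGF2 were highest and FXYD2 and CD24 lowest in the adrenal-type library. SLPI was at 10315 FPKM there and 56.1 ± 103 in the other 11, and IGF2, an imprinted growth factor, at 4686 against 15.96 ± 15.3. FXYD2 was at 1.33 FPKM there against 750 ± 375, and CD24 at 1.88 against 901 ± 454. The adrenal-type library was also lowest for SLC17A3, DDC, NAT8, BBOX1, CDHR5, PNCK, PRAP1, CXCL14 and SAA1. Without it the SD of log2 value fell from 2.49 to 1.67 in both NAT8 and CXCL14 and from 2.72 to 2.17 in SLC17A3. That SD changed little in SAA1 (3.89 to 3.82) and rose in KRT19 (2.74 to 2.87).

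Of 27 gene lists, 19 varied between tumours more than random lists of like expression (adjusted p below 0.05). The largest SDs belonged to proximal tubule genes (1.54, log2 scale), erythroid genes (1.52), replication-dependent histones (1.25) and the fibroblast and pericyte list (1.23), each at adjusted p = 0.000208, the smallest these random lists allowed. AQP1, a water channel of the proximal tubule, was at 216 ± 222 FPKM and GATM at 104 ± 74.9. ACTA2, a smooth muscle and pericyte actin, was at 475 ± 413 FPKM, TAGLN at 427 ± 379 and DCN, a collagen-binding proteoglycan, at 70.5 ± 90.7. HBA2 and HBB, the haemoglobin chains, were at 100.7 ± 92.3 and 95.3 ± 118 FPKM. HIST1H1C and HIST1H2BK were at 84.0 ± 96.8 and 31.3 ± 17.4. The erythroid score rested on 3 of 6 listed genes and the histone score on 8 of 18. The library highest for histones (2.04) was lowest for cell cycle genes (-0.73). Capture of histone transcripts in these poly-A libraries was not told apart from their level. HIF targets had an SD of 1.10 over 12 libraries and 0.317 without the adrenal-type library, which scored -3.37 against -0.11 to 0.90 in the others. In the 11, NDUFA4L2 was at 1432 ± 839 FPKM and LDHA at 725 ± 244, against 15.0 and 90.6 in that library.

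Immune and vascular lists were among the 19. Endothelial genes had an SD of 1.06, with PLVAP at 357 ± 240 FPKM, ENG at 161 ± 72.2 and CLDN5 at 45.5 ± 66.9 (26.8 ± 17.6 without its highest library). The B and plasma cell list (SD 0.912) was led by IGJ at 48.6 ± 123 FPKM and DERL3 at 5.73 ± 8.64. It rested on 1 library, which scored 2.41 against 0.477 or less in the others, and without which the SD was 0.537 (adjusted p = 0.0769), IGJ was at 13.2 ± 13.7 FPKM and DERL3 at 3.31 ± 2.24. T cell genes had an SD of 0.679 (CD4 39.7 ± 19.4, CD3E 9.94 ± 5.67, CD3D 6.32 ± 4.52 FPKM) and cytotoxic genes 0.584 (NKG7 16.5 ± 9.27, CST7 9.56 ± 4.90, GZMB 4.26 ± 3.06). Macrophage genes had an SD of 0.652 (C1QB 276 ± 175, C1QA 263 ± 133, MARCO 7.95 ± 17.6), neutrophil genes 0.668 (S100A9 43.9 ± 32.0, S100A8 19.6 ± 12.3) and MHC class II genes 0.674 (CD74 2392 ± 1102, HLA-DRA 940 ± 452, IFI30 318 ± 399.99). Immune checkpoint genes had an SD of 0.537 (HAVCR2 23.9 ± 14.2, IDO1 22.7 ± 21.6), the type I interferon list 0.525 (BST2 217 ± 176, IFI27 158 ± 103) and the TNF and NF-kB list 0.646 (SOD2 1094 ± 711, NFKBIA 113 ± 43.1, CXCL1 16.5 ± 25.4). MARCO and CXCL1 were at 3.06 ± 4.87 and 10.6 ± 16.03 FPKM without their highest library. Likewise without the highest library of each, C1QB was at 231 ± 86.9, C1QA at 232 ± 82.3 and CD4 at 34.9 ± 10.5 FPKM. The adrenal-type library widened the spread of IFI30 and BST2, which were at 214 ± 187 and 173 ± 87.6 FPKM in the other 11.

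Among the remaining lists past the threshold, immediate early genes had an SD of 1.06 (DUSP1 788 ± 504, ZFP36 367 ± 277, FOSB 55.6 ± 74.1 FPKM). Lipid storage and uptake genes had an SD of 0.694 (APOE 1014 ± 971, PLIN2 424 ± 287, FABP7 70.8 ± 105), cell cycle genes 0.499 (TYMS 28.3 ± 13.1, MCM2 8.41 ± 4.17, UBE2C 6.83 ± 4.54) and cytosolic ribosomal proteins 0.481 (RPL3 1519 ± 533, RPL13 1333 ± 534, RPS19 492 ± 248). The ribosomal list did not pass when any 1 of 4 libraries was left out (adjusted p = 0.0582 to 0.128). The 8 lists not past the threshold were podocyte (SD 0.465; SYNPO 109 ± 49.3, PODXL 48.1 ± 27.04), OXPHOS subunits (0.367; COX7C 559 ± 191, COX4I1 337 ± 118), MHC class I (0.342; B2M 3498 ± 1036, HLA-E 615 ± 143), heat shock (0.260; HSPB1 848 ± 287, HSPA8 321 ± 120), JAK-STAT components (0.259; STAT6 70.5 ± 17.9, SOCS3 92.3 ± 70.6), death receptor (0.202; TNFRSF1A 103 ± 26.7), chromatin regulators (0.187; SMARCA4 20.9 ± 4.23, BAP1 20.6 ± 7.78, PBRM1 7.01 ± 6.08) and Pol II elongation (0.102; SSRP1 40.6 ± 8.34, RDBP 36.4 ± 5.71). STAT6, BAP1 and PBRM1 were highest in the adrenal-type library, and at 65.9 ± 8.78, 18.8 ± 4.71 and 5.32 ± 1.75 FPKM in the other 11. Without the adrenal-type library 21 lists passed, OXPHOS (adjusted p = 0.00018) and MHC class I (adjusted p = 0.0136) in addition. With z-scores, which give each gene the same weight, 21 lists passed, 17 of them shared with the 19. The lipid (adjusted p = 0.256) and B and plasma cell (adjusted p = 0.0577) lists did not. Chromatin regulators (adjusted p = 0.00045), OXPHOS (adjusted p = 0.000169), MHC class I (adjusted p = 0.00567) and Pol II elongation (adjusted p = 0.0414) passed with z-scores alone among these 12 libraries.

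**Figure D2:**
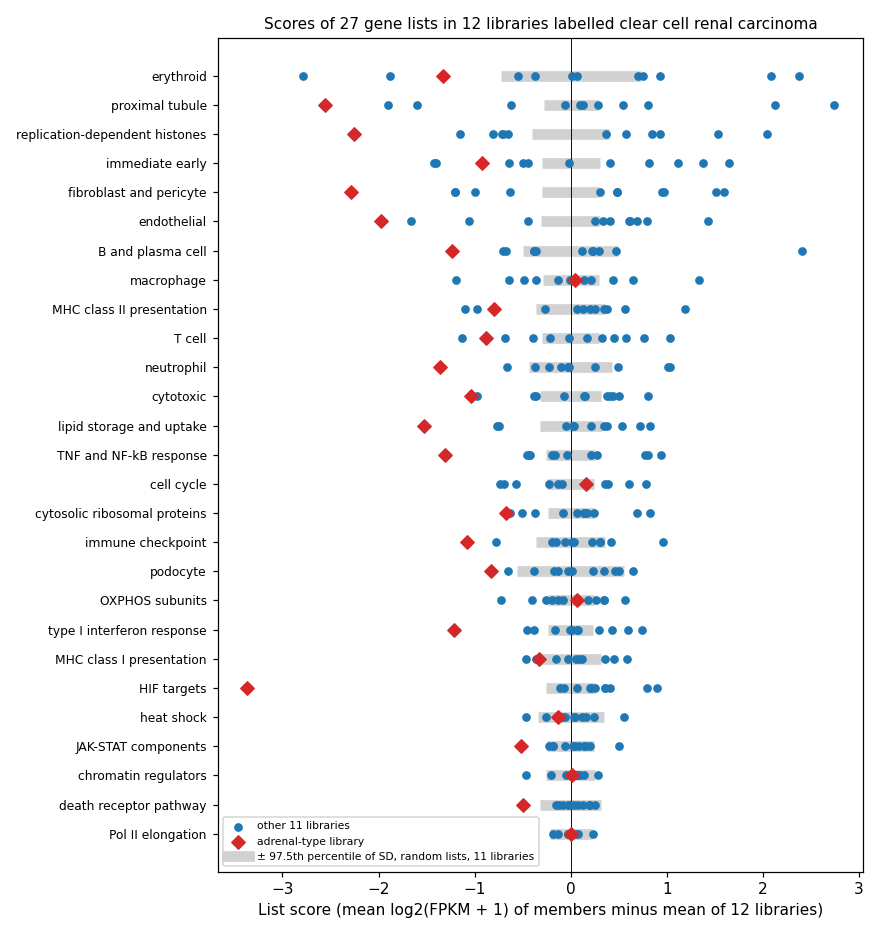
Scores of 27 gene lists (mean log2(FPKM + 1) of members minus the mean of 12 libraries, horizontal axis) for each library, with the adrenal-type library as a red diamond and the other 11 as blue points. Grey bars span plus and minus a high percentile of the SD of random lists over the 11 libraries, and the HIF target score of the adrenal-type library is -3.37.

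The series title names transcriptional fidelity, and the length index asked whether long genes were low in some tumours and which lists went with it. No list score was correlated with the index past the threshold over 12 libraries (0 of 27). By r the endothelial list came nearest, with r = 0.73 (permutation p = 0.0061, adjusted p = 0.11) and rho = 0.66 (permutation p = 0.0237). The podocyte list had r = 0.69 (permutation p = 0.0137, adjusted p = 0.11) and a larger rho of 0.71 (permutation p = 0.0115). Cell cycle genes had r = -0.67 (adjusted p = 0.11), chromatin regulators 0.68 (adjusted p = 0.11) and immediate early genes 0.61 (adjusted p = 0.172). Values for the interferon list (r = 0.16, adjusted p = 0.906), JAK-STAT components (0.13, adjusted p = 0.934) and the TNF and NF-kB list (-0.35, adjusted p = 0.725) were not past the threshold. Without the 2 tumours farthest from the median index, r was 0.51 for endothelial genes and 0.03 for chromatin regulators, so the latter rested on those tumours. Without the adrenal-type library 2 lists passed, endothelial (r = 0.87, permutation p = 0.00067, adjusted p = 0.0181, rho = 0.70, permutation p = 0.0203) and podocyte (r = 0.79, adjusted p = 0.0472, rho = 0.75). The podocyte score rested on 4 genes and did not vary more than random lists over these 11 (adjusted p = 0.175 in the spread test). Without a further library, the one with a trace of adrenal genes, 0 lists passed (endothelial r = 0.84, adjusted p = 0.0546). The adjusted p for rho of both was 0.275 over the 11, and r without the 2 farthest tumours was 0.70 and 0.52.

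**Figure D3:**
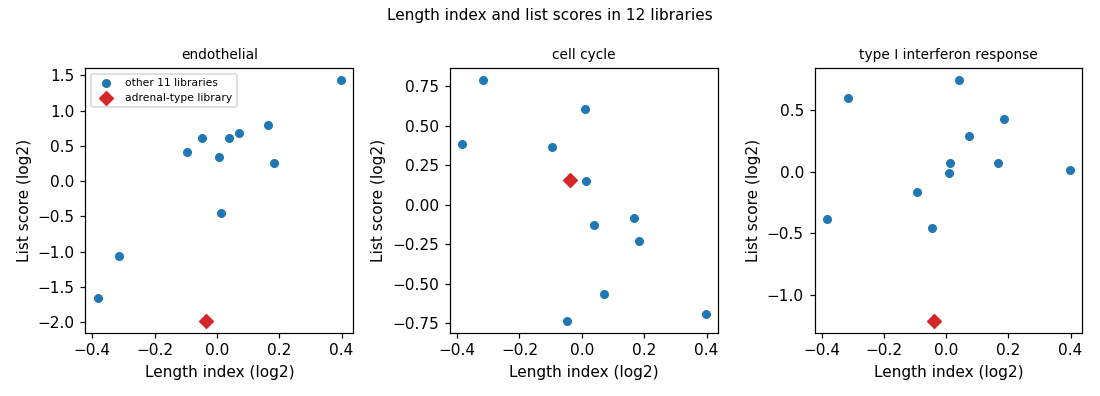
List scores (log2, vertical axis) against the length index (log2, horizontal axis) in 12 libraries for endothelial, cell cycle and type I interferon genes, the adrenal-type library as a red diamond and the other 11 as blue points. The endothelial relation has r = 0.73 over 12 libraries and 0.87 over 11.

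Single genes that followed the length index included endothelial genes. Of 10741 genes outside the long and short gene sets that define it, 4 rose with the index in limma, 0 fell, and 1337 had an unadjusted p under 0.05. PTPRB, an endothelial receptor phosphatase (chromosome 12, 70515866 to 70637440), rose by 1.24 ± 0.19 (SE) log2 per SD of the index (adjusted p = 0.0373). MMRN2, an endothelial matrix protein (chromosome 10, 86935540 to 86969481), rose by 0.84 ± 0.12 (adjusted p = 0.0373). LRRC8C, a volume-regulated channel subunit (chromosome 1, 89633072 to 89769903), rose by 0.56 ± 0.08 (adjusted p = 0.0373) and DNAJB4, a chaperone (chromosome 1, 77979175 to 78017964), by 0.63 ± 0.10 (adjusted p = 0.0387). C16orf7, CARD14 and FAHD2B had the smallest p among negative slopes and were not past the threshold (-0.45, -0.90 and -0.59; adjusted p = 0.0647, 0.0924 and 0.0924). Of the endothelial list, 9 genes lay outside the sets that define the index. Over all genes 0 of them passed, and 8 rose when adjusted over those 9 alone. In the same way 5 of 16 cell cycle genes fell, and 0 over all genes. The scores of these lists had r = 0.73 and -0.67 with this index in the same libraries. Counts adjusted over a list alone restate that and are not separate support. Leaving out any 1 of 6 libraries gave 0 rising genes.

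Without the adrenal-type library, 99 genes rose and 19 fell, and these included all 4 above. HSPA12B, GPR116, ITGA6, GATA2, RC3H2 and FAM107A were among the 10 of smallest p that rose, FAM107A by 1.32 ± 0.22 and ITGA6, a laminin receptor chain, by 0.86 ± 0.13. SLC6A8, the creatine transporter, fell by 1.16 ± 0.22 log2 per SD, C10orf99 fell by 2.07 ± 0.38 and F2, prothrombin, fell by 1.31 ± 0.26. OSR1, STK36, HPS3, ZNF683, ELF3, C16orf7 and CARD14 were the other 7 of smallest p that fell. In this fit 5 of the 9 endothelial genes outside the defining sets rose, with PECAM1 at 0.80 ± 0.13, TEK at 0.97 ± 0.16 and TIE1 at 0.75 ± 0.12 (adjusted p = 0.0285 each). All 9 rose when adjusted over those genes alone, which restates the correlation of their score with the index. When 1 more library was left out in turn, the number of genes past the threshold ranged from 0 to 189, so the count rested on single libraries.

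T cell and cytotoxic genes rose and fell together. Their scores had r = 0.86 (permutation p = 0.00034, adjusted p = 0.00408) and rho = 0.83 (permutation p = 0.00126), the only 1 of 12 pairs past the threshold, with r = 0.75 without the 2 farthest tumours. Cytotoxic genes had r = 0.65 with immune checkpoint genes, 0.63 with MHC class I genes and 0.63 with the interferon list (adjusted p = 0.0679 each). Macrophage and MHC class II genes had r = 0.71 (adjusted p = 0.0578), and T cell genes had r = 0.48 with macrophage genes and 0.37 with B and plasma cell genes (adjusted p = 0.176 and 0.272). HIF targets had r = 0.48 with endothelial and 0.40 with proximal tubule genes (adjusted p = 0.185 and 0.272). Endothelial genes had r = 0.61 with the fibroblast and pericyte list (adjusted p = 0.0719), cell cycle genes -0.04 with proximal tubule genes (adjusted p = 0.914), and Pol II elongation 0.54 with chromatin regulators (adjusted p = 0.142). Without the adrenal-type library the T cell and cytotoxic pair had r = 0.81 (adjusted p = 0.0236) but rho = 0.59 (permutation p = 0.062, adjusted p = 0.372), and the macrophage and MHC class II pair passed (r = 0.77, adjusted p = 0.0368). Without the 2 farthest tumours of the 11 these pairs had r = 0.53 and 0.37, so both rested in part on those tumours. Other pairs also changed without the adrenal-type library, and none of them passed. HIF targets then had r = -0.41 with endothelial and -0.42 with proximal tubule genes, cytotoxic genes 0.38 with the interferon list, 0.45 with immune checkpoint and 0.57 with MHC class I genes. T cell genes had 0.24 with B and plasma cell genes, endothelial genes 0.41 with the fibroblast and pericyte list, and cell cycle genes 0.06 with proximal tubule genes.

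Genes that rose with the cytotoxic score included CD247 and LCK, parts of T cell receptor signalling. Of 13273 genes outside the list, 5 rose in limma, 0 fell, and 1201 had an unadjusted p under 0.05. CD247, the zeta chain of the T cell receptor, rose by 0.66 ± 0.10 (SE) log2 per SD of the score (adjusted p = 0.0291), and LCK, the kinase that phosphorylates it, by 0.73 ± 0.12 (adjusted p = 0.0452). SPN rose by 0.62 ± 0.08 (adjusted p = 0.016), GZMM, a granzyme, by 0.70 ± 0.10 (adjusted p = 0.0288) and PTPRCAP by 0.77 ± 0.12 (adjusted p = 0.0452). GNG7, GULP1 and MEIS2 had the smallest p among negative slopes, with adjusted p = 0.158, 0.16 and 0.306. Adjusted over the list alone, 11 of 12 T cell genes, 7 of 10 MHC class II genes and 3 of 7 checkpoint genes rose, and 1, 0 and 0 over all genes. Without the adrenal-type library limma called 0 genes and 448 had an unadjusted p under 0.05, with slopes of 0.55 ± 0.08 for SPN and 0.62 ± 0.10 for CD247 (adjusted p = 0.133 each). Over the list alone, 12 of 12 T cell genes, 0 of 10 MHC class II genes and 0 of 7 checkpoint genes then rose. The T cell and checkpoint scores had r = 0.86 and 0.65 with the cytotoxic score over the 12 libraries. Counts over a list alone are therefore not separate support. Leaving out any 1 of 4 libraries, that one included, gave 0 genes.

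Isoform use was compared with the length index through the entropy of isoforms given genes. It had a mean of 0.455 ± 0.034 bits (SD, n = 12) and a range of 0.398 to 0.536. It was not correlated with the index past the threshold (r = -0.31, permutation p = 0.312; rho = -0.04, permutation p = 0.904), and r was -0.44 without the 2 farthest tumours.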

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

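Results without the adrenal-type library together with a second library, and isoform entropy from named entries, were chosen after seeing the data. The number of varying lists stayed within 1.5 times of 19 under every alternative run (13 to 21). The count of list pairs went from 1 to 2 with median-of-ratios rescaling, 3 with a pseudocount of 0.25 and 0 with a minimum median of 10. The T cell and cytotoxic pair was not called at that minimum, where it may not have been tested. CST7 and CD3E, among the 2 members of highest mean in these lists, had medians of 9.065 and 9.585 FPKM. Lists with under 3 expressed members were not scored, so the counts at a minimum median of 10 may cover fewer lists and pairs. The count of lists following the length index went from 0 to 1 with length-matched scores, the endothelial list (r = 0.81, adjusted p = 0.0337). With median-of-ratios rescaling 1 gene fell with the length index and 1 with the cytotoxic score, against 0 for each. With no filter 1 gene rose with the cytotoxic score, against 5. Without the adrenal-type library and the one with a trace of its genes, 1 gene rose with the length index and 0 with the cytotoxic score. The causes were not tested. Leaving out each tumour gave 17 to 21 varying lists, 0 to 2 lists following the index, 1 to 7 pairs, 0 to 99 genes rising and 0 to 19 falling with the index, 0 to 11 rising and 0 falling with the cytotoxic score, and an isoform entropy r of -0.43 to 0.06. The 99 and 19 came from leaving out the adrenal-type library, and without each of 6 others the rising count was 0. Isoform entropy from named entries had r = -0.51 (permutation p = 0.0927). The planned stricter minimum and the restriction to genes with 2 isoforms were not run, because the isoform table does not pair transcripts with genes. Depth is unknown, so no counting error could be computed for low values.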

Other observations

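Several secreted proteins were abundant in 1 tumour and low in the rest, by a rule chosen after the values were seen (at least 100 FPKM and over 20 times the next library). SST, the hormone somatostatin, reached 2674 FPKM in 1 tumour against 21.9 in the next. FGA, a fibrinogen chain, reached 562 against 27.3 and IGFBP1 382 against 12.02 in the same tumour. MSLN reached 300.3 FPKM against 12.04 and APCS, the serum amyloid P component, 260.2 against 1.47. Of the 29 genes that met the rule, 22 belonged to the adrenal-type library and 7 to others.

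The tests of the adrenal-type library, of its trace in a second library and of chance orders were chosen after the results were seen, and both tests of the endothelial relation before, except that their ranges with 1 library left out were added after. The adrenal-type library was the first pattern weighed. A mixture of clear cell carcinoma with adrenal tissue would keep a share of the renal genes, but their median ratio to the other libraries was 0.00303. Whole adrenal gland would bring medulla genes, and 0 of TH, DBH, PNMT and CHGA were above the other libraries, though CHGB was at 85.4 FPKM. The adrenal cortex list was written after the library was seen, so the 8 of its 12 genes at 1 FPKM or more and above every other library restate the pattern, and adrenocortical tissue under a kidney tumour label stays open. No further explanation of this library was tested, and normal and tumour cortex were not compared.

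A second library held a trace of genes high in the adrenal-type library, in a nearly constant ratio. Without use of the second library, 17 genes were chosen of at least 50 FPKM in the adrenal-type library and a median in the other 10 under 0.1% of that level, though KLK11 reached 97.8% of it in 1 of the 10 and the other 16 genes up to 3.31%. In the second library 16 were at 0.574% to 1.25%, with an SD of log10 ratio of 0.0892, and INS-IGF2, which overlaps IGF2, was listed at 0, where a value of 0.01 FPKM gives an SD of 0.417, above the bound of 0.3, so the reading rests on leaving it out. Adrenal cells with independently set levels would scatter like renal genes between tumours. Of 55 pairs of libraries, 0 had an SD as small as 0.0892 over 14 renal genes (lowest 0.155, median 0.325). The SD of 0.417 with INS-IGF2 at 0.01 FPKM is above that median. This comparison therefore also rests on leaving that gene out, and adrenal cells of its own stay open for the second library. Carry-over of RNA, library or reads from the adrenal-type library may account for the trace, and tissue carried over between sections is not told apart from it.

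The third pattern was the relation of endothelial genes to the length index in the 11 libraries (r = 0.87). With transcript length held in a regression for each tumour, the span coefficient had r = 0.745 with the endothelial score. That r was 0.543 to 0.84 when 1 library was left out and 0.088 without the 2 farthest. The transcript length coefficient, with span held, had r = 0.606 (0.445 to 0.758 with 1 library left out) and 0.690 without its 2 farthest. Transcript length and RNA degradation therefore stay open. An index from the less variable part of the long and short genes kept r = 0.841 (0.793 to 0.877 with 1 library left out), which argues against variable long genes as its source. That test does not reach a larger share of endothelial cells that raises long genes whatever their spread, which stays open. Random orders of the index gave as many genes as the 4 observed in 2 of 100 (highest 12) over 12 libraries. Over 11 libraries they gave as many as 118 in 0 of 100 (highest 11). For the cytotoxic score over 12 libraries they gave as many as 5 in 0 of 100 (highest 3). The cytotoxic score over 11 libraries called 0 genes, and random orders gave up to 14. Index and score were computed from the same libraries as the genes tested, a link that random orders break. These counts therefore do not exclude chance, and single libraries changed them.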
